A study of Homo sapiens with 12 samples.

How the data were processed

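RNA was sequenced from A549 and H1299 cells, 2 established human lung cancer lines, each stably infected with a lentivirus that carries EGFP and a neomycin resistance gene. One arm of each line received the empty vector and the other the same vector with HIF1A-AS3, a long noncoding RNA transcribed antisense to HIF1A, under a CMV promoter. Each of the 4 groups holds 3 libraries, 12 in all. Per the labels' protocols, total RNA was taken up in TRIzol and libraries were made with an mRNA kit. Nothing in the labels says whether the 3 libraries of a group came from separate infections or separate cultures, so the p-values measure the spread between these libraries, which may be technical. Likewise, the cells of an arm may descend from a single infection, in which case arm and infection cannot be told apart.

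The deposited values are raw counts of reads per gene, whole numbers that were not normalized. Per the submitters' processing notes, the tools named are Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.6, DESeq2 and edgeR, with genome build hg38. Whether the authors' counts used the strand of the read, and which annotation release they used, is not given in the sources used here. Reads from overlapping genes on opposite strands therefore cannot be told apart. The table lists 60649 genes, of which 60507 matched a name entry, and 21587 had no count in any library. Where identifiers shared a symbol, the one with most counts kept it. Columns were matched to samples by line, arm and number, with the abbreviation for the control columns read as the vector arm because it was the only one left.

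Library totals were 15834472 to 16765616 counts, so depth differed little between groups. Mitochondrially encoded genes took a mean of 4.62% of counts in A549 vector, 4.56% in A549 HIF1A-AS3, 3.64% in H1299 vector and 3.47% in H1299 HIF1A-AS3. Within each group, every pair of replicates differed by more than Poisson sampling (chi-square per degree of freedom 1.45 to 2.51), so no library was treated as a copy of another. Reads carry no molecular identifiers in these counts, so depth speaks for counting error only.

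Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr by group) in R 4.3.3. All 12 libraries entered one model of 4 groups with 8 residual degrees of freedom and no block. The contrasts were HIF1A-AS3 against vector in A549, the same in H1299, and the difference of both (A549 minus H1299). The filter kept 17997 genes, TMM factors were 0.919 to 1.09 and the common biological coefficient of variation was 2.66%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, for the 29 of 32 lists with at least 5 tested members. The lists, groups, tests, alternatives and the rule for naming genes were fixed before the data were examined.

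The rule names HIF1A-AS3, HIF1A and its other antisense genes. Per line it names the 10 called genes with the largest rise and the 10 with the largest fall among those with a symbol, a mean of at least 50 counts in that line and no overlap of CPM between arms. Per list it allows the 2 members with the smallest adjusted p in each direction, or the 2 with the smallest p where none is called. Across lines it takes 5 genes per direction called in both and 5 per direction with the largest difference. For the difference, the count minimum was applied to the mean over all 12 libraries and the overlap condition to the line with the larger change. The text names a selection of these genes, and some are not reported here.

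The test was tried on counts simulated from the real means, library sizes and dispersions, in 5 simulations. Changed genes were drawn among those with at least 50 counts in the line. In A549, 67.2% of genes changed 1.2-fold, 93.7% of those changed 1.5-fold and 99.4% of those changed 2-fold were called, with 17741 genes in the step. In H1299 the shares were 64.5%, 94.0% and 100%. When changed genes were drawn by their mean over both lines, so that some were hardly expressed in the line tested, recovery of 2-fold changes was 98.2% in A549 and 93.3% in H1299. Unchanged genes made up 6.9% of calls in A549, 9.7% in H1299 and 6.8% for the difference, above the nominal 5%, although 4.88%, 4.86% and 5.01% of unchanged genes had an unadjusted p under 0.05. In the same simulations 1 list was moved in A549 alone. Camera called it in 5 of 5 runs in A549 and for the difference and in 0 of 5 in H1299, and called 1 of 140 tests of other lists in each comparison. The simulated genes vary independently, which the real ones need not, so these runs do not show how often camera calls unmoved lists in real libraries.

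The alternatives were RLE and upper quartile scaling, no filter and a stricter one (CPM of at least 1 in 3 libraries), DESeq2 1.42.0 and limma voom, each line fitted alone, a replicate block, leaving out each library, an estimated correlation and fry for lists, and a 2-fold minimum. One alternative, leaving out genes of 19q, was added after the data were seen. Gene positions, GC content and length came from GENCODE release 29 on GRCh38.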

Results

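The series measured gene expression by RNA-seq in A549 and H1299 lung cancer cells with the empty lentiviral vector or with HIF1A-AS3, 3 libraries per group. Its title concerns a loop between this RNA and HIF-1α, chronic stress and macrophage inactivation. Total counts per library were 16478987 to 16579754 in A549 vector, 16721438 to 16765616 in A549 HIF1A-AS3, 15834472 to 15978689 in H1299 vector and 15902784 to 16057895 in H1299 HIF1A-AS3. The first principal component held 94.4% of the variance and separated the lines.

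HIF1A-AS3 was strongly raised in both lines. Counts were 30 to 32 in A549 vector and 10605 to 11150 in A549 HIF1A-AS3, a log2 fold change of 8.46 (SE 0.063, adjusted p 3.96e-42, edgeR). They were 8 to 15 in H1299 vector and 3832 to 4119 in H1299 HIF1A-AS3, a log2 fold change of 8.54 (SE 0.084, adjusted p 3.48e-38). The difference between lines, -0.08, was not called (adjusted p 0.919). HIF1A mRNA, which encodes the oxygen-regulated subunit of HIF-1, was at 784 ± 13.1 CPM in A549 vector and 786 ± 28.3 CPM with HIF1A-AS3 (SD, n = 3; log2 fold change 0.00, SE 0.030, adjusted p 0.992). In H1299 HIF1A fell slightly, from 240.5 ± 2.67 to 223 ± 8.44 CPM (SD, n = 3) (log2 fold change -0.11, SE 0.033, adjusted p 0.0219), and that call was lost without vector replicate 1, vector replicate 2 or HIF1A-AS3 replicate 1 (adjusted p up to 0.170). The difference between the lines, 0.11, was not called (adjusted p 0.135). In H1299 the 24 expressed genes in the 5 Mb of chromosome 14 that start at 60 Mb, HIF1A among them, had a median of -0.06. With genes shuffled along the genome, such medians reached up to 0.125 from the median of all genes. HIF1A-AS1, the other antisense gene, had 0 to 5 counts in every library and was not tested.

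The gene reported as HIF1A-AS3 is ENSG00000258667, on chromosome 14 from 61715558 to 61751097 of GRCh38, minus strand. GENCODE 29 names it HIF1A-AS2. HIF1A lies on the plus strand from 61695513 to 61748259. Of the 533 exonic bases of HIF1A-AS3, 0 lie in HIF1A exons, so spliced HIF1A reads are not shared with it, but intronic HIF1A reads could add to its low counts in vector libraries if strand was not used. As a check of the line labels, chosen after its values were seen, CDKN2A, which A549 lacks, had 0 or 1 count in each A549 library and 322 to 374 in H1299.

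**Figure D1:**
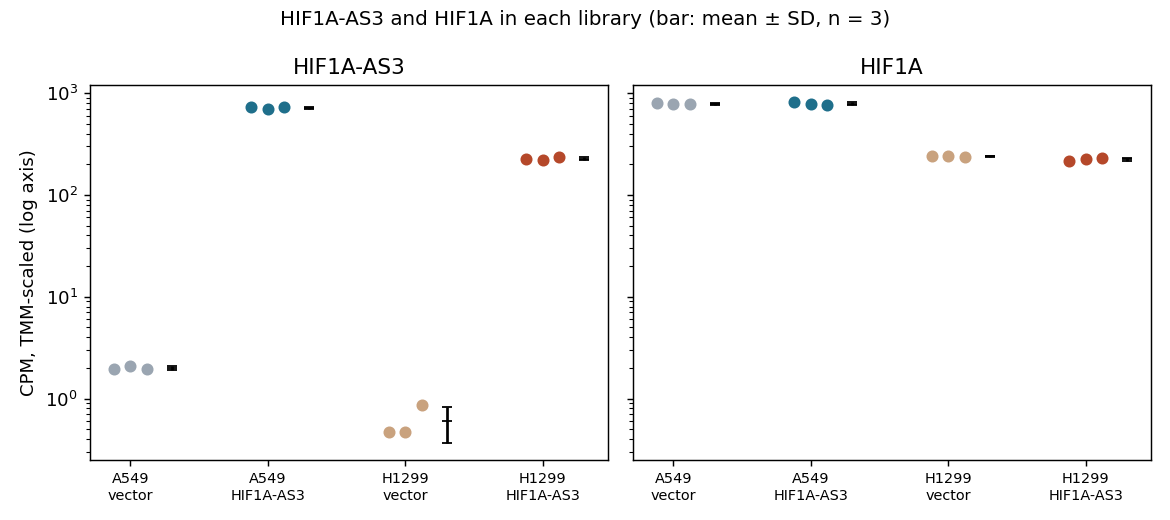
TMM-scaled CPM of HIF1A-AS3 (left) and HIF1A (right) on a log axis, with 1 point per library and the mean ± SD of 3 libraries beside each group. HIF1A-AS3 rose from a mean of 2.01 to 712 CPM in A549 and from 0.601 to 227 CPM in H1299, while HIF1A means were 784 and 786 CPM in A549 and 240.5 and 223 CPM in H1299.

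In A549 with HIF1A-AS3, NRF2 targets and matrix genes were higher and p53 targets lower as lists, calls that held with an estimated correlation. Mitosis genes were higher and heat-shock genes lower as lists at the preset correlation but not with an estimated one (adjusted p = 0.0647 and adjusted p = 0.0666 with an estimated correlation). Among genes with a mean of at least 50 counts in the line and no overlap of CPM between arms, the largest rises besides HIF1A-AS3 itself were those of CYP1A1, a xenobiotic-metabolizing monooxygenase (log2 fold change 1.28, SE 0.113), TJP1, a tight junction scaffold (1.21, SE 0.217), and ANPEP, a membrane aminopeptidase (0.83, SE 0.120). The next were the mitotic genes KIF2C (0.77), DLGAP5 (0.71), GTSE1 (0.66), CDK1 (0.66), TTK (0.65) and KIF14 (0.65). Among falls, the largest under the same conditions were those of CARS1, a cysteinyl-tRNA synthetase whose counts varied between replicates and are uncertain (56 to 107 in vector, 30 to 42 with HIF1A-AS3; -1.23, SE 0.317), CASS4 (-0.68), KDM8 (-0.55), CARMIL2 (-0.54), ESAM (-0.53), OVGP1 (-0.53), DUXAP10 (-0.52), PLEKHO1 (-0.51), CRABP2 (-0.51) and MYH14 (-0.48). In all, 560 genes rose and 360 fell of 17997 tested (edgeR), with a median change of 1.14-fold among called genes, and 32 changed at least 2-fold. Some called genes that these conditions leave out depend on 1 library. FDFT1 went from 1.525 to 0.397 without HIF1A-AS3 replicate 2, and CANX from -0.747 to -0.07 without 1 library. Such genes remain in the gene and list counts, and how many there are was not counted. DESeq2 called 609 genes. Of the 10 falls named, 9 (not MYH14) lost their call without at least 1 library, as did GTSE1 and TTK among the rises (adjusted p up to 0.272, for KDM8). The count itself was 548 without vector replicate 2, 571 without vector replicate 3, 543 without HIF1A-AS3 replicate 1 and 591 without HIF1A-AS3 replicate 2.

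G2/M and mitosis genes had the largest list median in A549, 0.33 on the log2 scale. Of 32 tested members 13 rose and 0 fell, or 19 and 0 adjusted over the list alone. Among them were MKI67, the Ki-67 proliferation marker (0.64, SE 0.078, adjusted p 2.0e-06), and TOP2A, the mitotic topoisomerase (0.45, SE 0.043). The list was called by camera (adjusted p 2.92e-13) but not with an estimated correlation (adjusted p = 0.0647 with an estimated correlation). The median CPM of the list was 6.44 in A549 vector and 79.2 in H1299 vector, so the rise in A549 started from a low level. RRM2, a subunit of ribonucleotide reductase, rose by 0.61 and PCNA, the replication clamp, fell by 0.18 on the log2 scale, and the DNA replication list they belong to was not called (1 of 37 rose, 1 fell, the same counts adjusted over the list alone, adjusted p 0.165).

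NRF2 targets, genes of the antioxidant response, rose together in A549. Of 30 members 15 rose and 0 fell, or 18 and 0 adjusted over the list alone, among them AKR1B10, an aldo-keto reductase (0.36, SE 0.040). The list was called by camera (adjusted p 2.15e-20) and kept its call with an estimated correlation (adjusted p = 0.00651 with an estimated correlation). Of 33 collagens and matrix genes 11 rose and 0 fell, or 15 and 1 adjusted over the list alone, including the laminin LAMA5 (0.23), with adjusted p 4.79e-10 by camera and adjusted p = 0.00948 with an estimated correlation. Of 29 p53 targets 8 fell and 1 rose, or 10 and 1 adjusted over the list alone. GADD45A (-0.22) and TP53INP1 (-0.18) fell, while TP53I3 rose (0.14, lost with DESeq2 and without 4 libraries, adjusted p up to 0.175; camera adjusted p 1.81e-06, adjusted p = 0.00651 with an estimated correlation).

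Chemokines and cytokines acting on macrophages had 5 of 19 members higher and 0 lower in A549, or 6 and 0 adjusted over the list alone. CXCL5, a neutrophil chemoattractant, rose by 0.32 (SE 0.038) and PTGES, the prostaglandin E synthase, by 0.30 (SE 0.043). Camera called the list (adjusted p 2.47e-05; adjusted p = 0.0657 with an estimated correlation). Heat-shock genes had 5 of 13 lower and 0 higher, or 7 and 0 adjusted over the list alone, among them DNAJB1 (-0.17) and DNAJB4 (-0.26) (camera adjusted p 2.47e-05; adjusted p = 0.0666 with an estimated correlation). Of 23 proteases and inhibitors 6 rose and 1 fell, or 7 and 1 adjusted over the list alone, including CTSD (0.35) and MMP14 (-0.27, lost without vector replicate 3, adjusted p 0.0615), with camera adjusted p 0.0122 and adjusted p = 0.0647 with an estimated correlation. Of 23 chaperones of the endoplasmic reticulum 4 fell and 0 rose, or 5 and 0 adjusted over the list alone, among them HSP90B1 (-0.17; camera adjusted p 0.0122, lost without vector replicate 2 with adjusted p 0.183; adjusted p = 0.124 with an estimated correlation). The largest fall among these chaperones was that of CANX, which depends on 1 library as given above. Of 23 cholesterol synthesis genes 1 rose and 1, SQLE, fell (-0.18), or 1 and 5 adjusted over the list alone (list lower, camera adjusted p 0.00919; adjusted p = 0.0647 with an estimated correlation). Of 45 cytosolic ribosomal protein genes 3 rose and 8 fell, RPL32 among them (-0.16, lost without HIF1A-AS3 replicate 1, adjusted p 0.0571), or 4 and 11 adjusted over the list alone; the list's median was -0.04 and its mean 0.02 (lower by camera, adjusted p 0.000459, lost without HIF1A-AS3 replicate 1 with adjusted p 0.199; adjusted p = 0.568 with an estimated correlation). Of 29 ATF4 targets of the integrated stress response 7 rose, TRIB3 by 0.17 among them, and 3 fell, or 9 and 4 adjusted over the list alone (camera adjusted p 0.0474, lost without H1299 vector replicate 2 or 3 or H1299 HIF1A-AS3 replicate 3 with adjusted p up to 0.0582; adjusted p = 0.385 with an estimated correlation).

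In H1299 more genes changed than in A549. At the preset correlation, lists of mitosis and DNA replication genes were lower and those of NRF2 and ATF4 targets higher. With an estimated correlation 0 lists were called in H1299 (adjusted p = 0.0596 with an estimated correlation for mitosis and for DNA replication genes, 0.0801 for NRF2 and 0.131 for ATF4 targets). Under the same conditions the largest rises besides HIF1A-AS3 were those of PPARGC1A, a coactivator of mitochondrial biogenesis (log2 fold change 1.48, SE 0.154), TNC, the matrix protein tenascin C (1.34, SE 0.095), RPS6KA6 (1.14, SE 0.106) and SERPINB1, an inhibitor of neutrophil proteases (1.05, SE 0.152). They were followed by EIF3CL (0.98), SPX (0.94), ZMAT1 (0.87), AMDHD1 (0.86) and BAALC-AS1 (0.86). These conditions leave out TFPI, with a larger rise, and FLRT3, with a larger fall, among others; both are given below. The largest falls under them were those of BMPER, a modulator of BMP signalling (-1.32, SE 0.108), THBS1, the matrix protein thrombospondin 1 (-1.24, SE 0.044), IGFBP4 (-1.03, SE 0.162), TGM2, a transglutaminase (-0.998, SE 0.049), and CBLN2 (-0.99, SE 0.117). The next were DKK1, a Wnt antagonist (-0.99, SE 0.092), SMG1P7 (-0.97), RIMS4 (-0.96), MN1 (-0.93) and ADORA2A-AS1 (-0.92). EIF3CL and SMG1P7 have near-identical relatives in the genome, so their counts are uncertain, and the call of EIF3CL was lost with DESeq2 (adjusted p 0.0627). In all, 1343 genes rose and 1455 fell (edgeR), with a median change of 1.16-fold among called genes, and 122 changed at least 2-fold. The balance turned with upper quartile scaling, where 56% of called genes were higher against 48% here. DESeq2 called 1913.

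G2/M and mitosis genes were lower in H1299, with a list median of -0.20 on the log2 scale. Of 32 members 22 fell and 0 rose, or 26 and 0 adjusted over the list alone. AURKA, a mitotic kinase, fell by 0.40 (SE 0.039, adjusted p 5.49e-09) and MKI67 fell by 0.26 (SE 0.031). Of 37 DNA replication genes 16 fell and 0 rose, or 21 and 0 adjusted over the list alone, among them UNG (-0.33) and UHRF1 (-0.30). Camera called both lists (adjusted p 3.62e-17 and 1.94e-08), and neither call held with an estimated correlation (adjusted p = 0.0596 with an estimated correlation for both). The non-polyadenylated histone genes had 2 of 20 lower, H2AC6 (-0.19) and H4C8 (-0.34), both lost without vector replicate 1 (adjusted p up to 0.0734), and 2 adjusted over the list alone (camera adjusted p 0.0328, lost without vector replicate 1 or 2 or HIF1A-AS3 replicate 1 or 3 with adjusted p up to 0.124; adjusted p = 0.131 with an estimated correlation).

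NRF2 targets rose in H1299 as well, 13 of 30 with 0 lower, or 16 and 1 adjusted over the list alone, among them FTH1, the ferritin heavy chain (0.40, SE 0.042), and OSGIN1 (0.27, SE 0.033). The list had adjusted p 2.06e-07 by camera and adjusted p = 0.0801 with an estimated correlation. Of 29 ATF4 targets 10 rose and 3 fell, or 12 and 3 adjusted over the list alone, including GDF15, a stress-induced cytokine (0.51, SE 0.057), SLC7A11, the cystine transporter (0.26, SE 0.036), and STC2 (-0.34, SE 0.041), with camera adjusted p 0.00118 and adjusted p = 0.131 with an estimated correlation. Of 19 glycolysis enzymes 7 rose and 1 fell, or 9 and 1 adjusted over the list alone, including ENO2 (0.24) and LDHB (0.23) (camera adjusted p 0.014, lost without vector replicate 1 with adjusted p 0.106; adjusted p = 0.356 with an estimated correlation). Heat-shock genes had 4 of 13 higher, HSPA8 by 0.23 among them, and 2 lower, the same counts adjusted over the list alone (camera adjusted p 0.0135; adjusted p = 0.345 with an estimated correlation).

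More matrix genes fell than rose in H1299. Of 33 collagens and matrix genes 12 fell and 3 rose, or 13 and 4 adjusted over the list alone. COL5A1 fell by 0.58 and COL5A2 rose by 0.74, and TNC rose while THBS1 fell as given above (camera adjusted p 0.0135; adjusted p = 0.131 with an estimated correlation). Of 27 mesenchymal genes 9 fell and 1 rose, or 11 and 3 adjusted over the list alone, including FN1, fibronectin (-0.68, SE 0.038), and CCN2 (-0.47, SE 0.044), with camera adjusted p 0.0135 and adjusted p = 0.131 with an estimated correlation. Of 23 proteases and inhibitors 8 fell and 1 rose, or 11 and 2 adjusted over the list alone, with TIMP2 at -0.26 and SERPINE2 at -0.24 (camera adjusted p 0.018; adjusted p = 0.106 with an estimated correlation). Of 22 macrophage checkpoint and phagocytosis signals 7 fell and 1 rose, or 9 and 3 adjusted over the list alone. PVR, the poliovirus receptor and TIGIT ligand, fell by 0.24 (SE 0.035), ANXA1 fell by 0.20 (SE 0.033) and ANXA5 rose by 0.09 (SE 0.028), a call lost without vector replicate 2 or 3 or HIF1A-AS3 replicate 1 or 2 (adjusted p up to 0.0889). Camera called that list (adjusted p 0.0106; adjusted p = 0.0801 with an estimated correlation).

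Of 23 cholesterol synthesis genes 4 fell and 0 rose in H1299, or 5 and 0 adjusted over the list alone, among them HMGCS1 (-0.21) (camera adjusted p 0.0185, lost without HIF1A-AS3 replicate 2 with adjusted p 0.0576; adjusted p = 0.131 with an estimated correlation). Of 45 cytosolic ribosomal protein genes 11 fell and 0 rose, or 12 and 0 adjusted over the list alone (camera adjusted p 0.00565; adjusted p = 0.579 with an estimated correlation). The median of 438 expressed genes of 19q was -0.15 in H1299, and without 19q genes, an alternative chosen after the data were seen, the ribosomal list was not called (adjusted p 0.0593), nor was it without vector replicate 2 or 3 or HIF1A-AS3 replicate 3 (adjusted p up to 0.0833). Of 15 mitochondrially encoded genes 0 were called, also 0 adjusted over the list alone, while camera called the list lower as a whole (adjusted p 0.014, lost without vector replicate 1 or 2 or HIF1A-AS3 replicate 3 with adjusted p up to 0.111; adjusted p = 0.579 with an estimated correlation).

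Targets of HIF-1 and hypoxia were not called as a list in either line, although without vector replicate 2 the list was called higher in A549 (adjusted p 0.0299). The test's sign differs from the list's median (-0.02) in A549 and from its mean (-0.02) in H1299. In A549, 4 of 38 rose and 1 fell, or 6 and 4 adjusted over the list alone, with STC2 at 0.18 and BNIP3, a mitophagy receptor, at -0.16, lost without vector replicate 2 or 3 or HIF1A-AS3 replicate 1 or 3 with adjusted p up to 0.274 (camera adjusted p 0.78). In H1299, 6 rose and 2 fell, or 7 and 2 adjusted over the list alone. BHLHE40 rose by 0.51 and DDIT4 by 0.22, and ADM fell by 0.39 on the log2 scale (camera adjusted p 0.196). Of 12 HIF pathway components 0 were called in A549 (adjusted p 0.519) and 3 fell in H1299, among them CITED2 (-0.34) and EPAS1, which encodes HIF-2α (-0.33), or 0 and 5 adjusted over the list alone (adjusted p 0.0695). With fry the list of HIF pathway components was called lower in H1299 (adjusted p 0.0179).

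The stress-hormone lists were not called by camera either. With fry, glucocorticoid-responsive genes were called lower in H1299 (adjusted p 0.0179). Of 23 genes of adrenergic and cAMP signalling 1 rose and 1 fell in A549, or 2 and 1 adjusted over the list alone (adjusted p 0.84), where NR4A1 fell by 0.46, and 3 rose and 3 fell in H1299 by either count (adjusted p 0.949). Glucocorticoid-responsive genes had 3 higher and 3 lower of 18 in A549, or 4 and 3 adjusted over the list alone (adjusted p 0.884), and 1 and 3 in H1299, or 2 and 5 (adjusted p 0.518). Immediate-early genes had 2 higher and 3 lower of 29 in A549 by either count (adjusted p 0.19) and 5 and 6 in H1299, or 7 and 9 adjusted over the list alone (adjusted p 0.519), where EGR1 rose by 0.76.

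The remaining lists were not called by camera. With fry, calls were gained in A549, each higher, for macrophage checkpoint signals (adjusted p 0.0023), mesenchymal genes (0.0115) and genes around HIF1A, HIF1A-AS3 included (0.000153). In H1299 fry called epithelial genes (adjusted p 0.0248) and HLA class I genes (0.0498) lower and genes around HIF1A higher (0.0248). In each line the 1 member of the list around HIF1A called higher over all genes was the overexpressed HIF1A-AS3 itself. The list's median was -0.03 in A549 and -0.07 in H1299, so these fry calls do not speak for the neighbouring genes. Of 31 interferon-stimulated genes 1 rose and 0 fell in A549, or 1 and 0 adjusted over the list alone (adjusted p 0.238), and 1 rose and 2 fell in H1299, or 1 and 2 adjusted over the list alone (adjusted p 0.865). Of 27 NF-kB targets 4 rose and 2 fell in A549, or 4 and 3 adjusted over the list alone (adjusted p 0.616), and 2 rose and 3 fell in H1299, or 2 and 3 adjusted over the list alone (adjusted p 0.949). Of 11 genes of HLA class I presentation 0 rose and 1 fell in A549, or 0 and 1 adjusted over the list alone (adjusted p 0.632), and 0 rose and 0 fell in H1299, or 0 and 0 adjusted over the list alone (adjusted p 0.519). The 1 fall in A549 was that of CANX (-0.747, but -0.07 without 1 library). Of 21 epithelial genes 2 rose and 0 fell in A549, or 4 and 0 adjusted over the list alone (adjusted p 0.167), and 1 rose and 4 fell in H1299, or 3 and 5 adjusted over the list alone (adjusted p 0.348). Of 35 nuclear oxidative phosphorylation genes 0 rose and 1 fell in A549, or 0 and 1 adjusted over the list alone (adjusted p 0.127), and 2 rose and 1 fell in H1299, or 1 and 1 adjusted over the list alone (adjusted p 0.949). Of 13 genes around HIF1A, HIF1A-AS3 included, 1 rose and 2 fell in A549, or 2 and 2 adjusted over the list alone (adjusted p 0.702), and 1 rose and 3 fell in H1299, or 1 and 3 adjusted over the list alone (adjusted p 0.645). Not called in A549 were macrophage checkpoint signals (3 of 22 higher and 1 lower, or 3 and 1 adjusted over the list alone, adjusted p 0.19). Likewise in A549 there was no call for mesenchymal genes (6 of 27 higher and 2 lower, or 6 and 4 adjusted over the list alone, adjusted p 0.0607). Likewise in A549 there was no call for glycolysis enzymes (3 of 19 higher and 0 lower, or 3 and 1 adjusted over the list alone, adjusted p 0.165). Likewise in A549 there was no call for mitochondrially encoded genes (0 of 15 higher and 1 lower, or 0 and 1 adjusted over the list alone, adjusted p 0.352). Nor was there in A549 for histone genes (0 of 20 higher and 0 lower, or 0 and 0 adjusted over the list alone, adjusted p 0.78). Leaving out 1 library gave calls in A549 for mesenchymal genes (adjusted p down to 0.0233), glycolysis enzymes (0.00057), mitochondrially encoded genes (1.4e-06) and oxidative phosphorylation genes (0.0156). In H1299 there was no call for p53 targets (5 of 29 higher and 5 lower, or 7 and 7 adjusted over the list alone, adjusted p 0.949). In H1299 there was no call for chemokines (2 of 19 higher and 2 lower, or 2 and 2 adjusted over the list alone, adjusted p 0.949). In H1299 there was no call for endoplasmic reticulum chaperones (2 of 23 higher and 1 lower, or 2 and 1 adjusted over the list alone, adjusted p 0.949). In several of these the sign of the test differs from that of the median or mean: in A549 for HLA class I, mesenchymal, glucocorticoid-responsive, HIF1A-neighbouring and alveolar genes, and in H1299 for interferon-stimulated, p53, chaperone, oxidative phosphorylation, glucocorticoid-responsive, adrenergic, HIF1A-neighbouring and alveolar genes. Markers of macrophages and blood cells stayed under 10 counts in every library for 10 of 14 genes, of fibroblasts for 8 of 12, of endothelial cells for 8 of 12 and of alveolar type 2 cells for 6 of 12, and the alveolar list, 5 genes tested, was not called (adjusted p 0.795 in A549 and 0.865 in H1299). Of the tested members of the other 3 marker lists, ESAM fell in A549 and COL6A3 in H1299, and 0 rose. Both calls were lost without at least 1 library (edgeR adjusted p up to 0.0799 for ESAM and 0.139 for COL6A3).

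**Figure D2:**
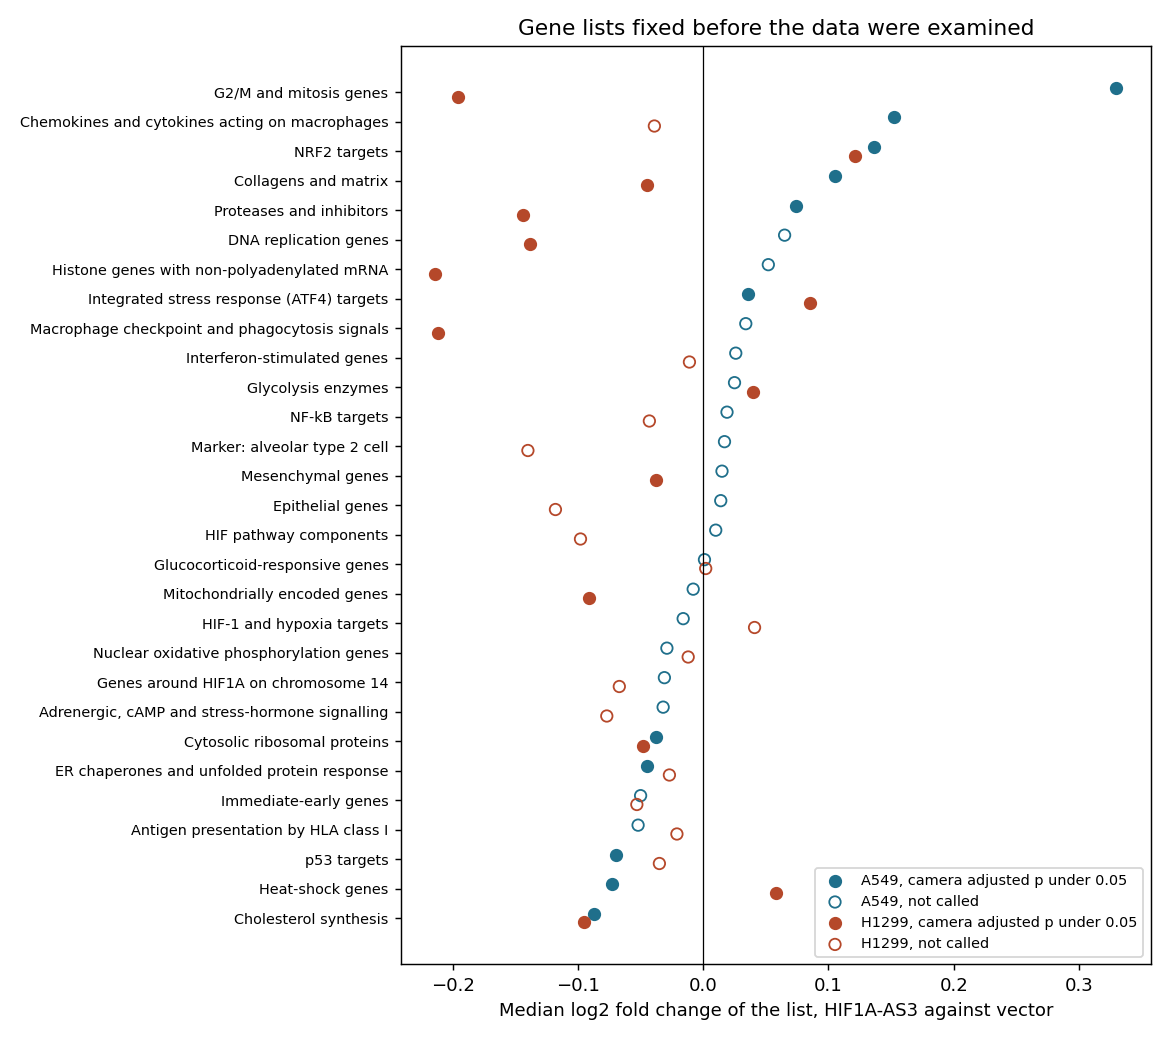
Median log2 fold change of HIF1A-AS3 against vector for the 29 lists tested, in A549 and in H1299, with filled points for lists called by camera at its preset correlation. The G2/M list lies at 0.33 in A549 and at -0.20 in H1299, and NRF2 targets lie above 0 in both lines.

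The change from vector to HIF1A-AS3 was not the same in the 2 lines. Since each arm may stem from a single infection, this does not by itself show a line-specific effect of HIF1A-AS3. The difference was called for 1450 genes, 841 with the higher change in A549 and 609 with the higher change in H1299 (edgeR interaction, 108 of them at least 2-fold; DESeq2 1044). FLRT3, an adhesion protein, fell from 74 to 76 counts to 1 to 5 counts in H1299 and was not called in A549 (difference 4.53, adjusted p 2.35e-11). TJP1 rose in A549 and fell in H1299 (difference 1.80), although its H1299 call was lost with DESeq2 (adjusted p 0.128) and without vector replicate 2 (adjusted p 0.103). XDH, xanthine dehydrogenase, moved likewise (1.71). PPARGC1A (-1.41) and TFPI, a coagulation inhibitor (-1.71), had the higher change in H1299, where TFPI was low, with a mean of 7.7 counts in vector and 26.3 with HIF1A-AS3. The 2 genes that ranked next to FLRT3 had at most 3 counts in each H1299 library and are not described.

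The change of G2/M and mitosis genes between the arms differed between the lines. The difference was called for 23 of 32 G2/M genes, each higher in A549, or 30 adjusted over the list alone, including MKI67 (0.90, adjusted p 3.8e-09) and TOP2A (0.68). The list's median difference was 0.54 (camera adjusted p 7.84e-23, adjusted p = 0.0226 with an estimated correlation). Camera also called the difference of collagens and matrix genes, heat-shock genes, DNA replication genes, proteases, macrophage checkpoint signals, mesenchymal genes and HIF pathway components. For collagens and for proteases the call held with an estimated correlation (adjusted p = 0.0226 with an estimated correlation for each), as it did for macrophage checkpoint signals (adjusted p = 0.0331 with an estimated correlation). It did not for heat-shock and DNA replication genes (adjusted p = 0.0533 with an estimated correlation for each), mesenchymal genes (adjusted p = 0.13 with an estimated correlation) or HIF pathway components (adjusted p = 0.199 with an estimated correlation). The difference was not called for NRF2 targets (adjusted p 0.394) or HIF-1 targets (adjusted p 0.12). For HIF-1 targets it was called, lower in A549, without A549 vector replicate 1 (adjusted p 0.0147) or A549 HIF1A-AS3 replicate 2 (adjusted p 0.022). Leaving out 1 library also gave calls of the difference, with adjusted p down to the value given, for p53 targets (0.0384), endoplasmic reticulum chaperones (0.0282), ATF4 targets (0.0282), mitochondrially encoded genes (0.00687) and ribosomal protein genes (0.0291). Of 60 splits of the libraries 12, the real one included, gave at least the 8 lists found, and 8 of the others kept the arms of 1 line.

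**Figure D3:**
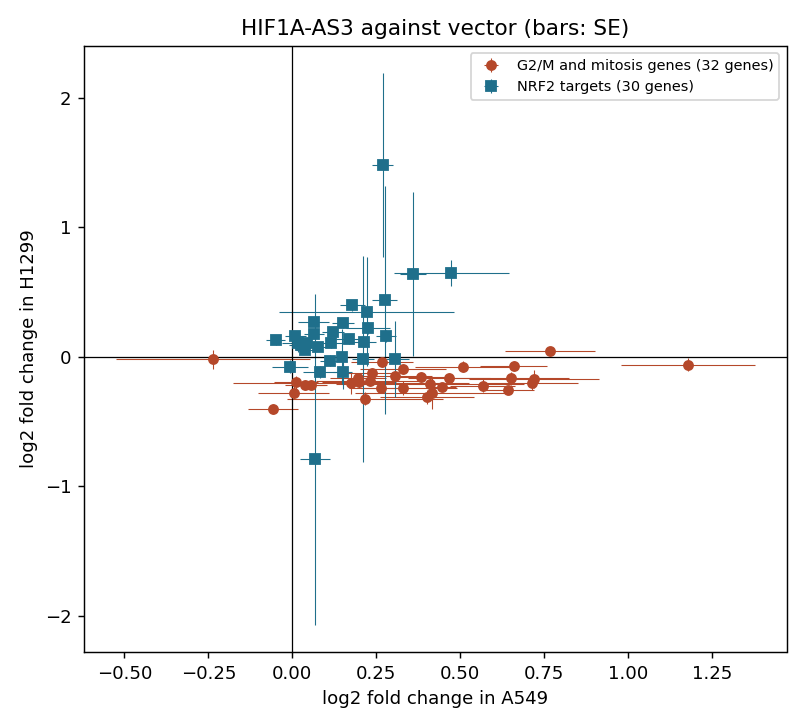
Log2 fold change of HIF1A-AS3 against vector in A549 (horizontal) and H1299 (vertical) for 32 G2/M genes and 30 NRF2 targets, with bars for the SE. G2/M genes lie mostly right of 0 and below 0, with medians of 0.33 in A549 and -0.20 in H1299, and NRF2 targets mostly right of and above 0; long vertical bars belong to genes with few counts in H1299.

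Genes changed the same way in both lines numbered 180, of which 104 rose and 76 fell. Among genes with a mean of at least 50 counts and no overlap of CPM between arms in each line, and ranked by the smaller of their 2 changes, those with the largest shared rise besides HIF1A-AS3 were KYAT3 (0.31 in A549 and 0.46 in H1299), SUCLG2, a subunit of succinyl-CoA ligase (0.33 and 0.31), PARP3 (0.32 and 0.29) and SSH3 (0.29 and 0.32). These conditions leave out CBLN2, which also fell in both lines but had 0 to 4 counts in A549. The largest shared falls under them were those of AOC3 (-0.47 and -0.43), CGN, the tight junction protein cingulin (-0.35 and -0.34), CHD5 (-0.33 and -0.40), SYT7 (-0.34 and -0.32) and HOXC13 (-0.30 and -0.34). Independent lists would share 41.8 rising and 29.1 falling genes, and the overlaps were larger (Fisher's exact test, 2-sided, p 1.91e-18 and 4.84e-15). By the same test, genes higher in A549 and lower in H1299 numbered 104 against 45.3 for independent lists (p 5.23e-16). Genes lower in A549 and higher in H1299 numbered 32 against 26.9 (p 0.31). The ratios to independent lists were 2.49 for shared rises and 2.61 for shared falls, and 2.3 and 1.19 for the opposite directions. Genes with few counts are hard to call in either line, which can raise such ratios, so these overlaps do not by themselves show a shared response. Across the tested genes without HIF1A-AS3, which are not independent replicates, the fold changes of the lines had a Pearson correlation of 0.006 and a Spearman correlation of 0.035. Leaving out 1 library of the A549 groups lowered the count of 180 by over 1.5 times in 3 cases, to 112 without vector replicate 2, 118 without vector replicate 3 and 109 without HIF1A-AS3 replicate 1. The calls of KYAT3, SSH3, CHD5, SYT7 and HOXC13 in A549 (adjusted p up to 0.204) and of SUCLG2, AOC3, SYT7 and HOXC13 in H1299 (up to 0.242) were lost without at least 1 library of that line.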

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

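The tests of the whole of chromosome 19, of 19q copies and of both explanations for ESRRG and LINC02684 were chosen only after the result was seen.

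The change from vector to HIF1A-AS3 differed between A549 and H1299 for 1450 genes, by the test of the difference itself. Of 60 of the 200 possible joint splits of the libraries, 1, the real one, gave as many genes. The highest other count was 596, in a split that keeps the arms of H1299. The other splits drawn mix vector and HIF1A-AS3 libraries in at least 1 line, which adds any effect of the arm to the spread. They therefore bear on whether libraries differ by arm at all, and cannot exclude chance for a difference between the lines. Regrouping A549 alone, with splits outside those 60 included, gave at most 662. Within a line there are too few splits (10) for a share under 0.05; the real count was 920 in A549 against at most 3 in another split, and 2798 in H1299 against at most 1.

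By the same test 8 lists differed at the preset correlation, and 4 of them with an estimated correlation: the call was lost for heat-shock and DNA replication genes (adjusted p = 0.0533 with an estimated correlation for each), mesenchymal genes (0.13) and HIF pathway components (0.199; also lost without 1 library in 6 of 12 fits, adjusted p up to 0.0978). Their median differences (A549 minus H1299, log2) were 0.54 for G2/M and mitosis genes, 0.20 for collagens and matrix genes, -0.14 for heat-shock genes, 0.17 for DNA replication genes, 0.29 for proteases and inhibitors, 0.23 for macrophage checkpoint signals, 0.15 for mesenchymal genes and 0.09 for HIF pathway components. For this count chance is not excluded: 12 of 60 splits, the real one included, gave at least 8 lists and the highest other count was 12. Of the other 11, 8 kept the arms of 1 line and so carry its change between arms, and 3 are among the 49 splits with neither line split as the samples are. In those 49 splits 0 genes and 0 to 9 lists were called for the difference, with at most 2 genes in A549 and 1 in H1299. Within a line the splits are too few (10), with 11 lists against 5 to 9 in A549 and 14 against 1 to 8 in H1299. These other splits gave at most 3 called genes in A549 and at most 1 in H1299. Camera at the preset correlation thus called lists where hardly any gene was called, and its adjusted p may be too small.

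Of the 102 genes given with values, 70 differed between the lines by the test of the difference, 41 with the higher change in A549 and 29 with the higher change in H1299. Most of these genes were picked for large changes, small p or the difference itself, so a high share follows from the choice. Over all 17997 tested genes the share was 8.06%. Higher in A549, with the difference in log2 fold change, were FLRT3 (4.53), TJP1 (1.80), XDH (1.71), TGM2 (1.46), BMPER (1.31), SMG1P7 (1.27), IGFBP4 (1.17), THBS1 (1.15), DKK1 (1.14), CYP1A1 (1.12) and MN1 (0.93). Then came DLGAP5 (0.92), MKI67 (0.90), ADORA2A-AS1 (0.85), TTK (0.82), KIF14 (0.79), RIMS4 (0.77), GTSE1 (0.74), CDK1 (0.73), KIF2C (0.72), RRM2 (0.71) and TOP2A (0.68). Then came FN1 (0.62), COL5A1 (0.61), UNG (0.51), STC2 (0.51), H4C8 (0.49), TIMP2 (0.48), ADM (0.46), EPAS1 (0.41), CCN2 (0.40) and CITED2 (0.40). Then came AURKA (0.34), SERPINE2 (0.33), PVR (0.33), UHRF1 (0.32), CTSD (0.30), LAMA5 (0.26), HMGCS1 (0.24), H2AC6 (0.24) and ANXA1 (0.21). Higher in H1299 were TFPI (-1.71), PPARGC1A (-1.41), TNC (-1.33), EIF3CL (-1.06), RPS6KA6 (-1.05), BAALC-AS1 (-1.0), ZMAT1 (-0.92), EGR1 (-0.91), SERPINB1 (-0.91), AMDHD1 (-0.88) and SPX (-0.74). Then came GDF15 (-0.56), BHLHE40 (-0.55), PLEKHO1 (-0.54), COL5A2 (-0.53), MYH14 (-0.52), DNAJB4 (-0.41), BNIP3 (-0.38), MMP14 (-0.38), TP53INP1 (-0.30), GADD45A (-0.30) and DDIT4 (-0.26). Then came HSPA8 (-0.24), FTH1 (-0.22), ENO2 (-0.22), RPL32 (-0.21), OSGIN1 (-0.21), HSP90B1 (-0.18) and ANXA5 (-0.18).

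G2/M and mitosis genes were higher with HIF1A-AS3 in A549 and lower in H1299, by the list median in each of the 3 libraries (0.41, 0.33 and 0.28 in A549 and -0.20, -0.18 and -0.18 in H1299), with 13 of 32 genes called higher in A549 and 22 lower in H1299, and neither list call held with an estimated correlation (adjusted p = 0.0647 and adjusted p = 0.0596 with an estimated correlation). Gene length and GC content are argued against as the whole cause, since 100.9% of the list median was kept after their trend was removed in A549 and 103% in H1299. H1299 RNA in the A549 libraries is argued against too, since genes with at most 3 counts in all over the A549 vector libraries stood in A549 HIF1A-AS3 at a median of 0.0678% of their H1299 level (bootstrap 95% interval 0.0391 to 0.109, 30 genes), where 2.04% would be needed. The growth state of the separately infected cultures cannot be told apart from HIF1A-AS3, since 0 of 4 terms for density, passage or infections are in the labels. An effect of HIF1A-AS3 that differs by line stays open as a hypothesis.

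Genes of 19q were lower with HIF1A-AS3 in H1299, with a median of -0.15 over 438 expressed genes against 0.00 over 10087 genes of other chromosomes and -0.01 for 19q in A549. The shift was not even along 19q. Its 5 Mb windows that start at 30 and 35 Mb lay at -0.062 and -0.079, and those that start from 40 to 55 Mb at -0.146 to -0.182. The 19p median was -0.04 in H1299, with 50 of 360 genes called lower and 15 higher. Removing the trend with gene length and GC content kept 86.7% of the distance of 19q from other chromosomes, which argues against that trend as the whole cause. The 19q median lay -0.10 from that of 19p (bootstrap 95% interval -0.118 to -0.084), which argues against a change of all of chromosome 19 alike. The bootstrap drew genes, not libraries, so the interval measures only the spread between genes, and neighbouring genes may not be independent. Fewer copies of 19q in part of the H1299 HIF1A-AS3 cells and an effect of HIF1A-AS3 on these genes cannot be told apart: 87.9% of the 19q genes lay below the median of other chromosomes, which any lowering of the whole region gives, and no DNA was measured. The test was first written to favour fewer copies at so high a share, and that reading was dropped after the value was known. Other regions of H1299 also shifted as blocks, as given under other observations, and the same limit holds for them.

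ESRRG, a nuclear receptor gene, had 0 counts in each H1299 vector library and 48 to 59 with HIF1A-AS3, while LINC02684 had 61 to 80 in H1299 vector and 0 with HIF1A-AS3; both were chosen after their values were seen. A549 RNA in the H1299 libraries is argued against, since ESRRG and LINC02684 together had 0 counts over the A549 libraries. Different founder cells in the H1299 arms could leave such a trace. These were the 2 genes in H1299 that went between 0 counts in one arm and at least 20 in each library of the other, and 0 did in A549, while FLRT3 came near it in H1299, with 74 to 76 counts in vector and 1 to 5 with HIF1A-AS3; founder cells and HIF1A-AS3 cannot be told apart without DNA or data on single cells.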

How the results depend on the processing

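The alternative without 19q genes was chosen only after the result was seen. HIF1A-AS3 rose in both lines under every alternative run (8.45 to 8.51 in A549 and 8.39 to 8.91 in H1299 over the fits without 1 library). DESeq2 called 609 genes in A549. A 2-fold minimum left 32 genes in A549, 122 in H1299, 108 for the difference and 1 changed the same way in both lines, as fewer genes can pass it. With an estimated correlation 3 lists were called in A549, 0 in H1299 and 4 for the difference. Genes around HIF1A in H1299 turned from lower to higher with fry (adjusted p 0.0248, against 0.645 with camera). That list holds the overexpressed HIF1A-AS3 itself (8.54), while its median was -0.07. The causes of these changes were not tested. Without 1 library, counts ranged from 543 to 993 genes in A549, 1982 to 2834 in H1299, 1060 to 1453 for the difference and 109 to 175 changed the same way, and from 10 to 14, 11 to 14 and 7 to 11 lists. A replicate block gave 798 genes in A549, 2552 in H1299 and 1288 for the difference, but the numbers do not pair the libraries (correlations of same-numbered libraries -0.045 to -0.02 in A549 and -0.05 to -0.026 in H1299). Without 19q genes the counts were 901, 2609 and 1364. Of 233 results of named genes, 157 kept their side of the threshold under every alternative fixed before the data were examined. Among the 233, 70 lost a call somewhere, 6 gained one and 0 reversed. Of 87 list results, 40 kept their side, 26 lost a call, 20 gained one and 1 reversed. A turn of sign counted as a reversal only where 1 of the 2 fits gave a call. Results without a call could change sign and still count as kept, as HIF1A in A549 did (-0.027 to 0.026). Genes that DESeq2 gave no adjusted p have no value there. With depths of 15834472 to 16765616 counts, simulated 1.2-fold changes were called in 67.2% of cases in A549 and 64.5% in H1299. These shares are for genes with at least 50 counts in the line. With genes drawn by their mean over both lines they were 58.5% and 60%.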

Other observations

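Changes in H1299 were grouped along the genome more than in A549. In 183 windows of 5 Mb with at least 20 genes, the window medians in H1299 had an SD of 0.0586 against 0.0265 with shuffled genes, and 9 windows lay beyond the largest shuffled value of 0.125. Of these, 4 lay on 19q and were lower (-0.18 to -0.15), and 5 were higher (0.13 to 0.17), those that start at 5 and 10 Mb of chromosome 1, at 5 and 25 Mb of chromosome 12 and at 100 Mb of chromosome 8. Windows near the higher ones went the same way in H1299. Those that start from 0 to 50 Mb of chromosome 1 lay at 0.036 to 0.138. Those that start from 0 to 25 Mb of chromosome 12 lay at 0.1 to 0.141, and that at 90 Mb of chromosome 8 at 0.123. In A549 the SD over 194 windows was 0.023 against 0.021, with 0 windows beyond. These windows were examined after the 19q values were seen.

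IGFBP4, TGM2 and DKK1, among the largest falls in H1299, rose in A549 (0.14, 0.46 and 0.15 on the log2 scale; adjusted p 0.00489, 3.43e-11 and 0.00221). STC2, a secreted glycoprotein, rose in A549 (0.18) and fell in H1299 (-0.34), and BNIP3 fell in A549 (-0.16, a call lost without vector replicate 2 or 3 or HIF1A-AS3 replicate 1 or 3, adjusted p up to 0.274) and rose in H1299 (0.22).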
